A study of Mus musculus with 80 samples.

How the data were processed

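The series holds 80 samples of mouse embryonic stem cells (ESC) and of embryoid bodies made from them, and values were used from 60. The other 20 samples (Hi-C, total H3, IgG and input controls, and the IgG arms of the sequential ChIP) were not analysed here. Per the labels, the conditional line was derived from C57Bl/6 blastocysts, carries floxed alleles of Mll2 (gene symbol Kmt2b) with a tamoxifen-inducible Cre recombinase, and was grown without feeder cells in serum and LIF. Wild type (WT) cells received the carrier and knockout (KO) cells 4-hydroxytamoxifen for 96 h, so deletion and drug treatment came together in every conditional comparison. A V6.5 line with catalytic-dead (CD) MLL2 and its own WT were grown on irradiated fibroblasts that were removed by pre-plating before use.

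For RNA-seq and PRO-seq the authors deposited 5 tables of FPKM values for 24508 gene symbols, 1 table per RNA day (0, 3, 6 and 9) and 1 for PRO-seq, each with 2 WT and 2 KO libraries. PRO-seq maps engaged RNA polymerase by a nuclear run-on with biotinylated nucleotides. Per the submitters' processing notes, RNA reads were aligned with TopHat and scaled with DESeq2 on mm9, and PRO-seq reads were trimmed with cutadapt 1.14 and Trimmomatic 0.33, aligned with Bowtie 1.1.2 and scaled with DESeq2. Drosophila nuclei were added to the PRO-seq run-on, per the labels' protocols, and the notes list the fly build dm3 beside mm9. The strand setting, the handling of multi-mapping reads and the annotation used for counting are not given in the sources used here. Genes that overlap, lie antisense to another gene or belong to multigene families are therefore reported as uncertain.

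FPKM steps of low genes were used to recover each library's reads on genes. Between 99.99 and 100% of the values above 0 came out as whole reads (tolerance 0.01), which gave 29018992 to 34476635 reads per RNA library and 16328488 to 20048186 per PRO-seq library. The deposited scaling matched a median of ratios between libraries of 1 table, not total reads and not the spike-in. On reads simulated from each table, 98.3 to 99.49% of genes were recovered. Chi-square statistics per degree of freedom between replicates were 8.86 to 50.8, so replicates differed by more than sampling noise and no library was a copy of another. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

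Differential expression was tested per table with limma 3.58.1 in R 4.3.3 (trend on mean expression, 2-sided, Benjamini-Hochberg) on log2(FPKM + 1), for genes with a mean FPKM of at least 1 over the 4 libraries. Fold changes are on that scale, which understates changes of low genes. A gene was called at an adjusted p under 0.05. Days were compared in 1 limma model over the 16 RNA libraries, as the difference between the KO effect at a later day and at day 0. Changes over time in WT or KO cells are a description only, because each day's table was normalized separately.

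Reads were simulated once around each gene's mean, with 200 seeded changes. Their spread was averaged over genes of similar mean, so differences in spread between such genes were left out. On these reads the test recovered 62.7, 83.6, 71.6 and 71.6% of 2-fold changes at days 0, 3, 6 and 9, and 64.2% in PRO-seq. At 1.5-fold the shares were 16.4, 59.7, 35.8, 9.0 and 9.0%, and at 4-fold 97.0, 92.4, 93.9, 97.0 and 90.9%. False calls made up 7.9, 8.2, 6.9, 10.6 and 14.2% of all calls in that order, above the nominal 5%. No simulated change was called in the wrong direction.

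A set of 21 gene lists (the targeted gene, Magohb, pluripotency, formative and primed epiblast, primitive streak, endoderm, cardiac and muscle mesoderm, neural ectoderm, blood and endothelium, Hox, other developmental factors, COMPASS, Polycomb, germline, p53 targets, 2-cell-like state, trophoblast, fibroblasts, immediate early genes, replication-dependent histones for RNA quality, and housekeeping) was tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of a comparison, for lists with at least 3 tested members. Camera with an estimated correlation and fry, which asks whether a list's genes move on balance 1 way, were run beside it. No list call held with an estimated correlation in any comparison. That form takes its degrees of freedom from the 4 libraries, so hardly any list could pass and its result alone does not count against a call. Polycomb at day 3 had an estimated correlation of -0.00108, below the preset, yet its camera adjusted p went from 0.00861 to 0.457. Estimates for called lists lay on both sides of the preset. They reached 0.719 for pluripotency at day 3 and 0.872 for germline at day 9. For lists above the preset, the camera p-values given here may be too small. Member counts adjusted over the list alone stand beside those over all genes for called lists, and only in part for the others. The 13 genes of the 2-cell-like state had 11 members in the tables and 0 tested in any comparison, and the 39 Hox genes had 0 tested in RNA.

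The genes named in each comparison were drawn from Kmt2b, Magohb, the 10 largest changes per direction among called genes whose WT and KO replicates did not overlap, and the 4 members of each list with the smallest p, of which mainly those past the test are printed. Named regions were the 5 highest-scoring WT MLL2 peaks and the 5 widest bivalent regions with an MLL2 peak and no KO H3K4me3 peak in both experiments. These rules, the lists, the main tests and most alternatives were fixed before the data were examined. Tests and alternatives added later are identified as such.

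For ChIP-seq and ATAC-seq the authors deposited 1 peak list per library, called without pooling, in mm9 coordinates. The score of each peak is the authors' own, is at least 50 in every list, and was used only to rank peaks within a list. Peak names in the deposited lists carry the word MACS, reads were aligned with Bowtie per the submitters' processing notes, and the caller's version and control library are not given in the sources used here. The sequential ChIP was deposited as 100 bp windows with a ratio-like score of at least 1. H3K4me3, H3K27me3, Suz12 and Ring1b were profiled in a pair of experiments. Per the labels, H3K4me3 was pulled down with different antibodies in experiments 1 and 2, experiment 2 included Drosophila chromatin (2.5% for histone marks, 0.08% for other targets), and the Ring1b samples included 2.5% human K562 chromatin. Whether the spike-ins entered the peak calls is not given in the sources used here.

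WT H3K4me3 peaks were merged per experiment and called bivalent where they overlapped a WT H3K27me3 peak of the same experiment. They were called H3K4me3-only where they overlapped no WT H3K27me3 peak of either experiment. Regions with an H3K27me3 peak in the other experiment alone were in neither class. H3K4me3 and H3K27me3 were measured in the experiment that had not defined the regions. Other targets were measured at regions of the same class in both experiments. A region carried a peak at an overlap of at least 1 bp. Shares are given with 95% Clopper-Pearson intervals, which cover counting error only. With 1 library per genotype and experiment, differences between these shares have no replicate check and no p-value. ATAC-seq had 3 libraries per genotype, compared by an exact 2-sided permutation test whose smallest possible p was 0.1. The overlap code matched a direct count in 400 of 400 simulated regions. Overlaps of called genes between comparisons with no shared library were tested with 1-sided Fisher's exact tests.

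Alternatives were a pseudocount of 0.1, no filter, a filter at 5 FPKM, quantile normalization, limma without trend, the replicate number as a block, a spread pooled over all 16 RNA libraries, each library left out in turn, an overlap of 0.5 of the region or peak, equal numbers of top-scoring peaks, and regions with a sequential ChIP window or an MLL2 peak. Voom weights on recovered reads, total-read scaling and the day 6 lists without KO replicate 1 were added after seeing the data. No mm9 annotation was used here, so peaks were not assigned to genes and a planned test of bivalent genes was not run. Chromosomes of genes came from a RefSeq table of GRCm38.p6, matched by symbol, without its coordinates. Computation outside R used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.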

Results

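Wild type and Mll2-deleted mouse embryonic stem cells were profiled by ChIP-seq, sequential ChIP (re-ChIP), ATAC-seq and PRO-seq, and RNA-seq followed their differentiation as hanging-drop embryoid bodies at days 0, 3, 6 and 9, day 0 being the stem cells themselves. MLL2, encoded by Kmt2b, is a histone methyltransferase that places H3K4me3, and the series asks what it does at bivalent promoters, where H3K4me3 lies together with the Polycomb mark H3K27me3. RNA-seq and PRO-seq had 2 libraries per genotype and day, ATAC-seq had 3 per genotype, and each ChIP target had 1 per genotype and experiment. Recovered reads on genes ranged from 29018992 to 34476635 per RNA library, with 5.56 to 7.51% taken by the top 10 genes, and from 16328488 to 20048186 per PRO-seq library, with 45.9 to 54.2% in the top 10. The depth behind the peak lists is unknown.

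The targeted protein was checked first. The WT library had 11084 MLL2 peaks and the KO library 264, and 68 of the WT peaks (0.613%) overlapped a KO peak. Whole-gene Kmt2b RNA does not isolate the deleted part of the gene. At day 0 it was 10.6 ± 1.69 FPKM in WT and 9.48 ± 0.0236 in KO (SD, n = 2; log2 fold change -0.14, SE 0.16, limma adjusted p = 0.814), and without WT replicate 2 the change was 0.005. Kmt2b fell at day 3 from 16 ± 1.51 to 6.97 ± 0.421 FPKM (-1.09, SE 0.10, adjusted p = 0.00464) and at day 6 from 15.4 ± 1.51 to 8.14 ± 0.376 FPKM (-0.84, SE 0.11, adjusted p = 0.00762). The values at day 9 were 14.4 ± 1.58 and 8.85 ± 2.70 FPKM (-0.67, adjusted p = 0.106), and the PRO-seq values were 12.9 ± 1.42 and 14.8 ± 1.42 FPKM (0.19, adjusted p = 0.497).

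MLL2 peaks were compared between bivalent and other H3K4me3 regions. Of 4139 regions that were bivalent in both experiments (median width 2077 bp), 2128 (51.4%, 95% interval 49.9 to 52.9) carried a WT MLL2 peak. Among 27102 regions with H3K4me3 alone in both experiments (median width 1764 bp), 6232 (23.0%, 22.5 to 23.5) did. In the other direction, 98.7% of WT MLL2 peaks overlapped a WT H3K4me3 peak and 37.3% a WT H3K27me3 peak. Re-ChIP, which pulls the same chromatin fragment down with both antibodies in turn, found a window at 88.5% (87.5 to 89.5) of bivalent regions in either order and at 3.8% (3.6 to 4.0) of H3K4me3-only regions. Experiment 1 gave 9754 bivalent and 33208 H3K4me3-only regions, and experiment 2 gave 4290 and 30434, with 19819 and 8080 WT H3K27me3 peaks behind them.

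The question at bivalent regions was how many keep an H3K4me3 peak in the KO. At bivalent regions defined in experiment 1 and measured in experiment 2, 94.8% (94.4 to 95.3) had an H3K4me3 peak in WT and 50.7% (49.7 to 51.7) in KO. The converse measurement in experiment 1 gave 99.0% (98.6 to 99.2) and 61.4% (59.9 to 62.8). At H3K4me3-only regions the shares were 81.9% in WT and 61.4% in KO in experiment 2, and 91.7% and 69.1% in experiment 1. Bivalent regions with a WT MLL2 peak kept an H3K4me3 peak in 77.2% (76.0 to 78.5) and 83.2% (81.6 to 84.8) of cases in experiments 2 and 1. Those without one had a KO peak in 28.5% (27.3 to 29.7) and 39.6% (37.5 to 41.7), from WT levels of 90.5 and 97.9%. WT peak scores differed between these regions. In bins of rising WT score in experiment 2, the share lost with and without an MLL2 peak was 91.9 and 93.1%, 85.9 and 76.7%, 55.5 and 42.6%, 5.5 and 8.7%, and 33.3 and 22.9%, and in experiment 1 it was 90.2 and 91.2%, 72.1 and 60.3%, 9.0 and 19.2%, and 22.7 and 30.8%. H3K4me3-only regions with an MLL2 peak were at 99.5% in WT and 94.5% in KO in experiment 2 and at 99.9% and 95.7% in experiment 1, and those without at 77.8% and 53.7%, and 89.5% and 62.2%. With equal numbers of top-scoring peaks the difference at bivalent regions was -35.1 points in experiment 2 and -33.2 in experiment 1, and at H3K4me3-only regions it was 0.5 and -3.7 points, in place of the -20.5 and -22.6 points of the full lists.

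**Figure D1:**
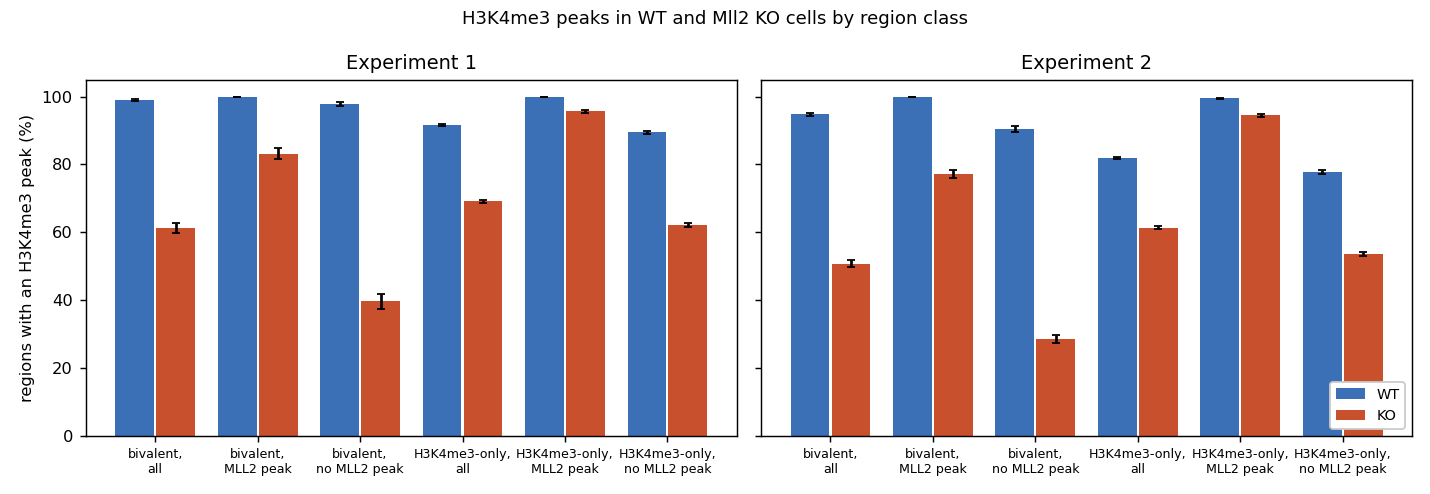
Percent of regions with an H3K4me3 peak (y axis, 0 to 100%) in WT and KO stem cells, for bivalent and H3K4me3-only regions, all of them and those with or without a WT MLL2 peak, in experiments 1 and 2, with bars for shares and whiskers for 95% Clopper-Pearson intervals. Bivalent regions stood at 94.8% in WT and 50.7% in KO in experiment 2.

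The 5 highest-scoring WT MLL2 peaks in mm9 lay at chromosome 15, 39774295 to 39776523 (the authors' score 2040.0), chromosome 18, 39648457 to 39652055 (1970.5), chromosome 6, 145197628 to 145199633 (1830.5), chromosome 3, 148650059 to 148654221 (1786.9), and chromosome X, 165757576 to 165758922 (1722.0). All 5 had no KO MLL2 peak, and all 5 kept an H3K4me3 peak in both KO libraries. Of the 2128 bivalent regions with an MLL2 peak, 343 had no KO H3K4me3 peak in either experiment. The widest of these were chromosome 2, 73114638 to 73119935 (5298 bp), chromosome 12, 57633812 to 57638320 (4509 bp), chromosome 4, 44723368 to 44727790 (4423 bp), chromosome 17, 80111781 to 80116110 (4330 bp), and chromosome 3, 38783477 to 38787511 (4035 bp). Each carried H3K27me3 in both WT and both KO libraries. The genes at these positions were not assigned, since no mm9 annotation was used here.

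Catalytic-dead MLL2 in V6.5 cells was compared to ask whether the enzyme's activity, and not its presence, accounts for H3K4me3 at the same regions. The share of bivalent regions with an H3K4me3 peak was 99.0% in V6.5 WT and 81.8% (80.6 to 82.9) in CD cells, a difference of -17.2 points. At H3K4me3-only regions it was 89.4% and 61.3%, a difference of -28.1 points. Bivalent regions with an MLL2 peak stood at 100% in WT and 96.6% in CD, and those without at 98.0% and 66.1%. The CD list held 25891 peaks against 41008 in WT, and with equal numbers of peaks the differences were -10.8 points at bivalent and -6.0 points at H3K4me3-only regions, so the order of the classes turned. Line, feeder layer and allele all differ between the CD and KO comparisons, and the difference between them was not tested.

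H3K27me3 and Polycomb proteins did not follow H3K4me3 in a single direction. The H3K27me3 share of bivalent regions was 44.3% in WT and 51.9% in KO in experiment 2, and 97.7% and 98.3% in experiment 1, while it was 97.3% in V6.5 WT and 92.8% in CD cells. The WT share in experiment 1 left little room for a gain. The H3K27me3 lists held 19819 WT and 31018 KO peaks in experiment 1, and 8080 and 8263 in experiment 2. Bivalent regions with an MLL2 peak carried H3K27me3 in 48.0% of cases in WT and 61.2% in KO in experiment 2 and in 99.3% and 99.5% in experiment 1, and those without in 41.2% and 44.1%, and 96.2% and 97.2%. Suz12, a core subunit of Polycomb repressive complex 2, was at 79.7% of bivalent regions in WT and 81.5% in KO in experiment 1, and at 90.1% and 84.8% in experiment 2. Ring1b, the ubiquitin ligase of Polycomb repressive complex 1, was at 94.1% and 88.1% in experiment 1 and at 44.8% and 69.4% in experiment 2, where the lists held 2242 WT and 4640 KO peaks. With equal numbers of peaks the Ring1b differences were -4.7 and 2.4 points and the Suz12 differences -3.8 and -4.8 points, so the mean Ring1b difference of 9.28 points became -1.17. At bivalent regions with an MLL2 peak the Suz12 differences were 3.8 and -1.4 points, which turned their mean from -1.79 to 1.22, and an overlap of 0.5 moved the mean H3K27me3 difference in the KO from 4.10 to 9.97 points.

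RNA polymerase II, active marks and CTCF were measured once per genotype. The form of the polymerase phosphorylated at serine 5 had a peak at 79.6% of bivalent regions in WT and 66.7% in KO, and at 48.0% and 67.1% of H3K4me3-only regions. Total polymerase (RPB1) stood at 19.1% and 30.9% of bivalent and at 48.8% and 61.5% of H3K4me3-only regions. H3K27ac, a mark of active promoters and enhancers, was at 7.9% and 5.0% of bivalent and at 56.8% and 47.7% of H3K4me3-only regions (79.3% and 62.4% with an MLL2 peak, 50.1% and 43.3% without). H3K36me3, which follows transcription, was at 4.6% and 5.0% of bivalent regions, and the insulator protein CTCF at 34.7% and 31.7%. With equal numbers of peaks the serine 5 difference at bivalent regions moved from -12.9 to -24.0 points, the RPB1 difference from 11.79 to 5.19 points and the H3K27ac difference from -2.90 to -0.31 points. At H3K4me3-only regions they moved from 19.1 to 9.3, from 12.7 to 5.8 and from -9.1 to -3.8 points.

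ATAC-seq, which maps open chromatin, asked whether bivalent regions lose accessibility in the KO. An ATAC peak lay at 49.93% ± 4.64 of bivalent regions in WT and 44.34% ± 7.51 in KO (SD, n = 3 per genotype), a difference of -5.59 points (exact permutation p = 0.4). At H3K4me3-only regions the difference was -1.20 points (exact permutation p = 0.7). The bivalent share minus the H3K4me3-only share of the same library was 0.62, 0.48 and 0.72 points in WT and -8.63, -0.86 and -1.86 in KO, so every KO library lay below every WT library. Its difference was -4.39 points with an exact permutation p of 0.1, the smallest this design allows, and -4.72 points (exact p = 0.1) with 26601 peaks per library. With that number the difference was -2.66 points at bivalent regions (exact permutation p = 0.2) and turned to 2.07 points at H3K4me3-only regions (exact permutation p = 0.1). Without KO replicate 1 the difference of classes was -1.96 points and that of bivalent regions -1.27 points, and without WT replicate 2 that of bivalent regions was -3.41 points.

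**Figure D2:**
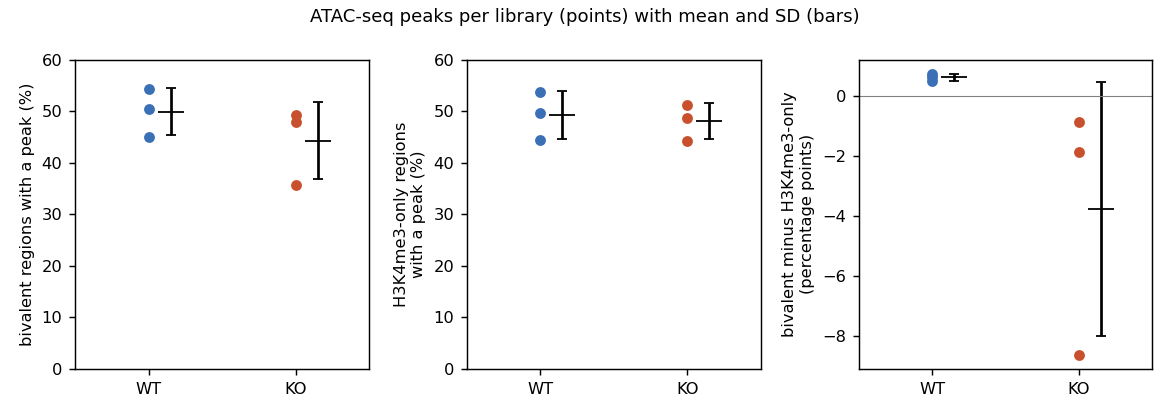
Percent of bivalent regions and of H3K4me3-only regions with an ATAC peak, and the difference of both in percentage points, for each of 3 WT and 3 KO libraries (points), with group means and SDs. The KO differences were -8.63, -0.86 and -1.86 points and the WT differences 0.62, 0.48 and 0.72.

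RNA of the stem cells at day 0 asked which genes depend on MLL2 before differentiation. Magohb, a paralogue of the exon junction component Magoh described before as dependent on Mll2, fell from 26.1 ± 3.26 to 2.85 ± 1.00 FPKM (SD, n = 2; log2 fold change -2.84, SE 0.21, limma adjusted p = 0.00348). Apcdd1, an inhibitor of Wnt signalling, rose from 3.14 ± 0.516 to 17.7 ± 3.58 FPKM (2.17, SE 0.19, adjusted p = 0.005). Of 11318 genes tested, 158 were higher and 218 lower in the KO, 79 and 120 of them by at least 1 on the log2 scale. The other 9 of the 10 largest decreases were Tspan6 (-2.74, SE 0.30), Sh3bgrl (-2.43, SE 0.31), the deubiquitinase Otud6a (-2.38, SE 0.16), and the RNA export factor relative Nxt2 (-2.38, SE 0.14), followed by the autophagy gene Gabarapl1 (-2.30, SE 0.19), the G protein subunit Gng10 (-2.17, SE 0.18), the kinase Stk26 (-2.13, SE 0.21), Cdca7l (-2.11, SE 0.16) and Tspan7 (-2.09, SE 0.20), with adjusted p between 0.00237 and 0.0125. Among the increases were carbonic anhydrase Car2 (8.41 ± 1.49 to 34.2 ± 7.56 FPKM; 1.90, SE 0.20, adjusted p = 0.00746), AI662270 (1.85, SE 0.21), the imprinted growth factor Igf2 (1.16 ± 0.360 to 5.94 ± 0.272 FPKM; 1.70, SE 0.18), Prss45 (1.68, SE 0.17) and the autoimmune regulator Aire (1.61, SE 0.22). Pramef17 (1.80), Gm13128 (1.75), Akr1c13 (1.63) and Akr1c18 (1.62) belong to multigene families and are uncertain.

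The p53 target list was the 1 list called at day 0 of 17 tested, with 2 of 17 members higher and 0 lower (4 and 0 adjusted over the list alone), a median of 0.25 and a camera adjusted p of 0.000609. Its adjusted p = 0.584 with an estimated correlation. Btg2 (9.43 ± 0.651 to 22.8 ± 4.78 FPKM; 1.18, SE 0.18, adjusted p = 0.0193) and the kinase Plk2 (1.06, SE 0.20, adjusted p = 0.0339) rose, and Perp (0.58, adjusted p = 0.0639) and Mdm2 (0.63, adjusted p = 0.0671) did not pass. Of 15 germline genes 4 fell and 1 rose (8 and 3 adjusted over the list alone; camera adjusted p = 0.0919). The lower ones were the meiotic gene Tex11 (-2.03, SE 0.18, adjusted p = 0.005), the synaptonemal complex gene Sycp1 (-1.24, SE 0.17), the piRNA pathway gene Mael (-1.37, SE 0.23) and the germ cell helicase Ddx4 (-0.93, SE 0.18, adjusted p = 0.0382), the last named after its value was seen. Tex101 rose (1.27, SE 0.22, adjusted p = 0.028). With the replicate number as a block, the germline list was called lower at day 0 (camera adjusted p = 6.21e-05). The cardiac and immediate early lists were then called higher (0.0378 each), though replicate numbers do not establish pairs. Of 22 pluripotency genes 1 fell, Dppa3 (15.4 ± 3.92 to 5.55 ± 0.438 FPKM; -1.30, SE 0.20, adjusted p = 0.0193), while Nanog (-0.52, adjusted p = 0.204) and Sox2 (-0.46, adjusted p = 0.159) did not pass (camera adjusted p = 0.0919). Among 12 immediate early genes Ier3 rose (0.83, SE 0.16, adjusted p = 0.038).

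No member passed at day 0 in the lists of formative and primed epiblast (7 tested, camera adjusted p = 0.695), primitive streak (4, 0.69), endoderm (3, 0.196), cardiac and muscle mesoderm (6, 0.0919), neural ectoderm (8, 0.242) and blood and endothelium (3, 0.457). The same held for other developmental factors (7, 0.112), COMPASS and H3K4 enzymes (16, 0.572), Polycomb subunits (29, 0.877), trophoblast (6, 0.49), fibroblasts (4, 0.112), replication-dependent histones (12, 0.242) and housekeeping genes (13, 0.877). Adjusted over the list alone, 4 cardiac genes were higher and 1 lower, the epiblast, endoderm and neural lists each had 1 higher, and the trophoblast and housekeeping lists each had 1 lower. The Polycomb median was -0.00 with a mean of 0.02 and a camera direction of higher. Without WT replicate 1 or WT replicate 2 limma called 0 genes at day 0 (1575 and 1690 at an unadjusted p under 0.05, against 1753 with all libraries). Without the filter on low values it called 0 of 19339 (2942 unadjusted), while voom called 460 with the filter. A filter at 5 FPKM gave 72 and a spread pooled over the 16 RNA libraries 1134. Calls at day 0 therefore depend on the filter. With a library left out the spread comes from the other genotype alone, so those counts do not show which library the calls rest on. Of all tested genes, 43.3% had replicates that did not overlap between genotypes.

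PRO-seq of the same stem cell stage asked whether transcription itself changed. Magohb fell from 7.17 ± 2.11 to 1.39 ± 0.287 FPKM (SD, n = 2; -1.76, SE 0.20, limma adjusted p = 0.0281), and Ankrd37 fell from 14.1 ± 0.83 to 3.83 ± 0.693 FPKM (-1.65, SE 0.13, adjusted p = 0.0278). The retinal transcription factor Atoh7 (-1.68, SE 0.21), the sarcomere gene Actn2 (-1.55, SE 0.13), Cbr4 (-1.54, SE 0.15), 1700029J07Rik (-1.51, SE 0.13) and the retinol carrier Rbp4 (2.22 ± 0.589 to 0.128 ± 0.0674 FPKM; -1.50, SE 0.18) also fell, with adjusted p between 0.0278 and 0.0301. Rises included the ubiquitin-conjugating gene Ube2l6 (2.81 ± 0.464 to 9.15 ± 1.63 FPKM; 1.41, SE 0.16, adjusted p = 0.0281), 1700057H21Rik (2.07, SE 0.27), 1700042G07Rik (1.49, SE 0.15), Prss42 (1.30, SE 0.11) and Nuggc (1.30, SE 0.14). Of 14535 genes tested, 97 were higher and 121 lower. The precursors Mir7220 (2.15), Mir3089 (1.91), Mir6945 (1.67), Mir199a-1 (-1.79) and Mir20b (-1.61), the antisense gene Ptprtos (1.59) and the histone gene Hist1h2ba (-1.79) share reads with hosts, partners or copies and are uncertain. Genes lower at day 0 in RNA and in PRO-seq numbered 46, against 1.2 for independent lists (Fisher's exact p = 1.28e-66), and genes higher in both 26 against 0.8 (p = 2.72e-34). Across genes the fold changes correlated at r = 0.70, and genes are not independent replicates.

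The list of other developmental factors was called higher in PRO-seq. Of 20 tested, 3 were higher and 0 lower (6 and 0 adjusted over the list alone; median 0.26, camera adjusted p = 0.000469). They were Pax2 (4.55 ± 0.947 to 10.4 ± 0.813 FPKM; 1.05, SE 0.15, adjusted p = 0.0378), Gbx2 (24.5 ± 0.187 to 43.7 ± 4.64 FPKM; 0.80, SE 0.11, adjusted p = 0.0388) and Gata3 (1.02, SE 0.16, adjusted p = 0.0494). The pluripotency list was called lower (median -0.23, camera adjusted p = 0.00282) with 0 of 21 members past the limma threshold and 1 lower adjusted over the list alone. Its member with the smallest p, Nanog, was 109 ± 10.3 FPKM in WT and 69.0 ± 2.65 in KO (-0.64, SE 0.13, adjusted p = 0.0726). Immediate early genes were called higher (11 tested, 0 higher, 3 higher adjusted over the list alone; median 0.22, camera adjusted p = 0.0213), with Jun at 0.58 (adjusted p = 0.0654) and Nr4a1 at 0.52 (adjusted p = 0.0638). The 19 replication-dependent histones were called lower with 0 members past the threshold by either adjustment (median -0.17, camera adjusted p = 0.0213). Each of these 4 lists had an adjusted p = 0.76 with an estimated correlation.

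Other lists were not called in PRO-seq. In them the neural and epiblast factor Sox3 fell (3.64 ± 0.511 to 0.723 ± 0.0472 FPKM; -1.43, SE 0.14, adjusted p = 0.0278), as did Hoxd1 (-1.14, adjusted p = 0.0414), Tex11 (-1.13, adjusted p = 0.0314) and the trophoblast factor Tfap2c (-0.73, adjusted p = 0.0378), while Mesp2 rose (0.92, adjusted p = 0.0295). The camera adjusted p was 0.247 for the formative and primed epiblast (9 tested), 0.728 for the primitive streak (11) and for Hox genes (8), 0.662 for endoderm (6), 0.748 for cardiac (7) and 0.833 for neural genes (11). It was 0.447 for blood (9), 0.544 for COMPASS (16) and p53 targets (17), 0.758 for Polycomb (31), 0.548 for germline (11), 0.742 for trophoblast (4), 0.247 for fibroblast (3) and 0.627 for housekeeping genes (13). Median, mean and test differed in sign for neural genes (median -0.00, mean 0.01), COMPASS (0.01 and -0.04) and, between camera and fry, the primitive streak. With a PRO-seq library left out the spread comes from the other genotype alone, so the counts below do not show which library the calls rest on. Limma called 31 and 4 genes without WT replicates 1 and 2 and 0 without KO replicates 1 and 2 (1669 and 1758 unadjusted, against 2491 with all libraries). It called 0 without the filter (3527 unadjusted), 68 with a filter at 5 FPKM and 91 (40 higher, 51 lower) by total-read scaling, while voom called 850.

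At day 3 of differentiation 1081 genes were higher and 1275 lower in the KO embryoid bodies, of 11088 tested, with 107 and 185 by at least 1 on the log2 scale. Magohb fell from 24.4 ± 0.685 to 1.84 ± 0.788 FPKM (SD, n = 2; -3.19, SE 0.19, limma adjusted p = 0.00269), and Suclg2, a subunit of the mitochondrial succinyl-CoA ligase, from 26.3 ± 1.88 to 4.74 ± 0.344 FPKM (-2.25, SE 0.09, adjusted p = 0.00216). The kinase gene Pim2 rose from 48.1 ± 1.19 to 238 ± 77.3 FPKM (2.24, SE 0.21, adjusted p = 0.00505) and the intermediate filament gene Nes from 1.98 ± 0.119 to 9.41 ± 1.47 FPKM (1.80, SE 0.12, adjusted p = 0.00327). Further decreases were Nxt2 (-2.76, SE 0.09), the testis antigen gene Fmr1nb (37.6 ± 4.08 to 6.87 ± 2.30 FPKM; -2.32, SE 0.20), Mael (-2.15, SE 0.10), and Tspan6 (-2.14, SE 0.18), then the stress response gene Nupr1 (-2.10, SE 0.18), the fatty acid carrier Fabp5 (-1.98, SE 0.21), Crtac1 (-1.96, SE 0.34) and Ufsp2 (-1.94, SE 0.15). Further increases were the lysophospholipase Enpp2 (2.10, SE 0.25), the tight junction gene Cldn6 (9.94 ± 0.59 to 42.3 ± 12.3 FPKM; 1.96, SE 0.19), Pcdh1 (1.84, SE 0.20), Spink1 (1.74, SE 0.36), the proteoglycan gene Dcn (1.68, SE 0.14) and Vrtn (1.67, SE 0.18). Platr5 (1.74) and Ptprtos (1.64) overlap or lie antisense to other genes and are uncertain.

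At day 3 the pluripotency list was called lower and the epiblast list higher, neither with an estimated correlation nor with fry (fry adjusted p = 0.263 and 0.126). Of 22 pluripotency genes 11 were lower and 2 higher (14 and 2 adjusted over the list alone; median -0.58, camera adjusted p = 0.00488, adjusted p = 0.609 with an estimated correlation). Klf4 (11.3 ± 1.81 to 4.12 ± 1.28 FPKM; -1.27, SE 0.19, adjusted p = 0.0132) and Tcl1 (-1.03, SE 0.18) fell. Tdgf1 (0.56, SE 0.09) and Lin28a (0.44, SE 0.08), which stay on in the primed epiblast, rose. Of 11 formative and primed epiblast genes 3 were higher and 0 lower (7 and 1 adjusted over the list alone; median 0.53, camera adjusted p = 0.0144, adjusted p = 0.457 with an estimated correlation). They were Pou3f1 (8.63 ± 0.0277 to 23.8 ± 7.97 FPKM; 1.33, SE 0.21), the de novo DNA methyltransferase Dnmt3b (80.5 ± 6.10 to 180 ± 55.4 FPKM; 1.12, SE 0.20) and Sox3 (0.72, SE 0.16). Germline genes fell in 9 of 15 cases and 1 rose (10 and 2 adjusted over the list alone; median -0.89, camera adjusted p = 0.0018, adjusted p = 0.457 with an estimated correlation). Dazl (6.00 ± 0.399 to 1.22 ± 0.303 FPKM; -1.66, SE 0.13) and Tex11 (-1.80, SE 0.12) fell and Tdrd12 (1.33, SE 0.08) rose. Polycomb subunits were lower in 7 of 29 cases and higher in 0 (11 and 3 adjusted over the list alone; median -0.17, camera adjusted p = 0.00861, adjusted p = 0.457 with an estimated correlation). Among them were Suz12 (167 ± 1.87 to 98.4 ± 19.7 FPKM; -0.77, SE 0.13, adjusted p = 0.0173), Pcgf5 (-0.70, SE 0.10), Mtf2 (-0.49, SE 0.08) and Phf19 (-0.59, SE 0.11).

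The p53 targets rose in 7 of 17 cases and 1 fell at day 3 (11 and 1 adjusted over the list alone; median 0.33, camera adjusted p = 5.21e-05, adjusted p = 0.457 with an estimated correlation). The leading members were Perp (15.7 ± 0.109 to 44.6 ± 4.50 FPKM; 1.45, SE 0.09), Plk2 (1.09, SE 0.08), the cell cycle inhibitor Cdkn1a (32.2 ± 3.02 to 69.2 ± 3.45 FPKM; 1.08, SE 0.09) and Phlda3 (0.87, SE 0.08). Markers of another cell type were measured beside them. Fibroblast markers were higher in 3 of 4 tested cases by both adjustments (Dcn; Tagln 1.5, SE 0.15; Thy1 1.06, SE 0.19; list median 1.28, camera adjusted p = 0.0217, adjusted p = 0.457 with an estimated correlation), in a line grown without feeders. Of 8 histone genes, the list for RNA quality, 2 were higher (4 adjusted over the list alone; median 0.36, camera adjusted p = 0.0144, adjusted p = 0.535 with an estimated correlation), Hist1h4i (1.30) and Hist1h1c (0.73), both from multigene families and uncertain. Other developmental factors had 2 of 10 higher by both adjustments (median 0.30, camera adjusted p = 0.0228, adjusted p = 0.486 with an estimated correlation), among them Wt1 (0.60, SE 0.09).

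Lists not called by camera at day 3 held members that passed the gene test. In neural ectoderm (9 tested, 3 higher and 1 lower, camera adjusted p = 0.274, fry adjusted p = 0.037), Nes, Olig2 (0.53, adjusted p = 0.0223) and Sox11 (0.42, adjusted p = 0.0407) rose and Tubb3 (-0.41, adjusted p = 0.0343) fell. In the trophoblast list (6, 3 and 3, 0.64) Krt18 (1.28) and Krt8 (1.31), keratins of simple epithelia in general, rose. In endoderm (3, 2 and 1, 0.409) Dab2 (1.1, adjusted p = 0.0342) and Apoa2 (0.52) rose and Sox7 (-0.67) fell. In the primitive streak list (5, 1 and 1, 0.613) Nodal (0.25) rose and Eomes (-0.66) fell. In COMPASS (16, 0 and 2, 0.303) the H3K4 methyltransferase Kmt2c (-0.64, adjusted p = 0.0133) and Rbbp5 (-0.35) fell, and in housekeeping genes (13, 1 and 1, 0.18) B2m fell (39.2 ± 0.873 to 16.5 ± 4.82 FPKM; -1.23). Jun (0.94) rose among 9 immediate early genes (camera adjusted p = 0.271). Des (1.11) rose among 2 cardiac genes and Pecam1 (-0.80) fell among 2 blood and endothelium genes, lists too short for a list test. Calls at day 3 numbered 249 without WT replicate 1, 151 without WT replicate 2, 959 without the filter and 1425 with a filter at 5 FPKM, against 2356, and 68.0% of all tested genes had replicates that did not overlap between genotypes. Between day 0 and day 3, 138 genes were lower on both days, against 21.0 for independent lists (Fisher's exact p = 4.02e-93), and 59 were higher on both, against 11.9 (p = 1e-27).

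At day 6 the collagen gene Col4a1 had the largest increase in the KO and Magohb the largest decrease. Col4a1 rose from 2.02 ± 0.225 to 27.1 ± 26.9 FPKM (SD, n = 2; 2.77, SE 0.66, limma adjusted p = 0.0422) and Lama1 from 0.802 ± 0.0519 to 13.1 ± 13.1 FPKM (2.56, SE 0.63, adjusted p = 0.0451). Magohb fell from 20.8 ± 1.53 to 0.976 ± 0.182 FPKM (-3.47, SE 0.12, adjusted p = 0.000368) and Fmr1nb from 35.5 ± 6.18 to 2.54 ± 0.401 FPKM (-3.36, SE 0.15, adjusted p = 0.000678). Spink1 (2.73, SE 0.54), the endocytic receptor Cubn (2.60, SE 0.51), Col4a2 (2.39, SE 0.61), the endocytic adaptor Dab2 (2.24, SE 0.50) and the endoderm transcription factor Gata4 (0.386 ± 0.195 to 3.83 ± 2.82 FPKM; 1.67, SE 0.38) rose as well. KO replicate 1 stood above KO replicate 2 at these genes. Without KO replicate 1 the changes were 1.58 for Col4a1, 1.43 for Lama1, 1.29 for Col4a2, 1.04 for Gata4, 1.71 for Cubn, 1.78 for Spink1 and 1.37 for Dab2, and without KO replicate 2 they were 3.97, 3.69, 3.49, 2.31, 3.5, 3.69 and 3.12. Enpp2 (2.03, SE 0.30), Pga5 (1.62, SE 0.35) and Sema6a (1.06 ± 0.168 to 5.35 ± 1.49 FPKM; SE 0.18, adjusted p = 0.00549) complete the 10 largest rises. Further decreases were Nxt2 (-2.85, SE 0.14), Mael (-2.60, SE 0.14), Suclg2 (-2.33, SE 0.11) and Gng10 (-2.27, SE 0.27). So were the germ cell transcription factor Sohlh2 (4.14 ± 1.05 to 0.189 ± 0.0475 FPKM; -2.10, SE 0.17), the nucleotide enzyme Dctd (-2.06, SE 0.18) and 2210409E12Rik (-2.06, SE 0.13). Fthl17f (-2.04), of a multigene family, is uncertain.

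Of 11184 genes tested at day 6, 604 were higher and 886 lower, 58 and 174 of them by at least 1 on the log2 scale. Formative and primed epiblast genes rose in 7 of 11 cases with 0 lower (8 and 0 adjusted over the list alone; median 0.50, camera adjusted p = 2.92e-05). Among these were Pou3f1 (0.90, SE 0.08), Dnmt3b (114 ± 0.696 to 199 ± 18.7 FPKM; 0.79, SE 0.08), Otx2 (0.78, SE 0.10) and Fgf5 (3.63 ± 0.364 to 8.54 ± 1.84 FPKM; 1.03, SE 0.15). Pluripotency genes were lower in 7 and higher in 2 of 22 cases (12 and 2 adjusted over the list alone; median -0.41, camera adjusted p = 0.00607). Nanog (194 ± 19.9 to 111 ± 22.3 FPKM; -0.82, SE 0.14), Zfp42 (-0.83, SE 0.11) and Tcl1 (-1.33, SE 0.15) fell and Tdgf1 (0.47, SE 0.07) rose. Germline genes fell in 11 of 13 cases and 1 rose, by both adjustments (median -1.04, camera adjusted p = 4.3e-08). They included Dazl (5.50 ± 0.0378 to 0.681 ± 0.245 FPKM; -1.96, SE 0.14), Tex11 (-1.80, SE 0.14) and Sycp1 (-1.57, SE 0.12). The p53 targets rose in 6 of 17 cases with 0 lower (10 and 0 adjusted over the list alone; median 0.29, camera adjusted p = 2.59e-05), including Cdkn1a (0.70, SE 0.07), Phlda3 (0.65, SE 0.07), Btg2 (0.79, SE 0.09) and Plk2 (0.94, SE 0.13). All 4 lists had an adjusted p = 0.361 with an estimated correlation.

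Another 6 lists were called at day 6 with a camera adjusted p of 0.0416 each. With the replicate number as a block the primitive streak list lost its call (0.0572). Endoderm had 2 of 4 higher, Dab2 and Gata4 (3 adjusted over the list alone; median 1.06), and the primitive streak 1 of 6, Wnt3 (0.596 ± 0.0421 to 2.79 ± 0.140 FPKM; 1.25, SE 0.12; 3 adjusted over the list alone; median 0.25). Fibroblasts had 2 of 4, Dcn (0.98) and Thy1 (0.45) (3 adjusted over the list alone; median 0.72), and histones 1 of 8 by both adjustments, Hist1h4i (0.83; median 0.34). Polycomb subunits had 3 of 29 lower by both adjustments, Suz12 (141 ± 5.58 to 93.2 ± 1.23 FPKM; -0.59, SE 0.07, adjusted p = 0.00569), Mtf2 (-0.44) and Jarid2 (-0.46) (median -0.07). These 5 lists had an adjusted p = 0.361 with an estimated correlation. Other developmental factors had 1 of 12 higher and 1 lower, the lower being Meis2 (-0.68) (3 and 1 adjusted over the list alone; median 0.27, adjusted p = 0.582 with an estimated correlation). Without KO replicate 1, an alternative added after seeing the data, the endoderm list had 3 members higher, a median of 0.80 and a camera adjusted p of 0.00664, the germline list 7.53e-11, Polycomb 0.11 and housekeeping genes 0.018.

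Among lists not called at day 6, neural ectoderm (9 tested, camera adjusted p = 0.115) had Sox11 (0.67), Nes (1.37) and Olig2 (0.86) higher and Tubb3 (-0.42) lower. Blood and endothelium (3, 0.0827) had Pecam1 (-0.83) and Tek (-0.47) lower. COMPASS (16, 0.454) had Cxxc1 (0.43) higher, and immediate early genes (9, 0.294) had Jun (0.98) higher. Housekeeping genes (13, 0.168) had B2m (31.8 ± 0.806 to 12.9 ± 1.04 FPKM; -1.24) lower, and trophoblast (6, 0.588) had 0. Des (1.01) rose among 2 cardiac genes. The calls of day 3 and day 6 shared 645 lower genes, against 98.8 for independent lists, and 421 higher genes, against 57.2, with r = 0.84 across genes. Calls numbered 179 without WT replicate 1, 157 without WT replicate 2, 2684 without KO replicate 2, 333 without the filter and 894 with a filter at 5 FPKM, against 1490. Of all genes tested, 61.8% had replicates that did not overlap between genotypes.

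At day 9 the laminin gene Lama1 had the largest increase and Fmr1nb the largest decrease. Lama1 rose from 0.821 ± 0.356 to 17.4 ± 10.9 FPKM (SD, n = 2; 3.21, SE 0.39, limma adjusted p = 0.0126) and Afp, the fetal serum protein made by visceral endoderm, from 0.0231 ± 0.0121 to 3.05 ± 1.37 FPKM (1.94, SE 0.25, adjusted p = 0.0148). Fmr1nb fell from 33.5 ± 4.35 to 2.64 ± 0.367 FPKM (-3.24, SE 0.15, adjusted p = 0.00152) and Magohb from 19.8 ± 2.05 to 1.59 ± 0.396 FPKM (-3.01, SE 0.16, adjusted p = 0.00152). The proteoglycan gene Srgn (1.37 ± 0.0077 to 17.8 ± 7.78 FPKM; 2.93, SE 0.27), the calcium-binding gene S100g (2.70, SE 0.40), Col4a2 (2.66, SE 0.45), the water channel Aqp8 (2.53, SE 0.32), Col4a1 (2.44, SE 0.50), Cubn (2.23, SE 0.17), Aadac (1.56, SE 0.15) and Cltb (1.47, SE 0.18) rose. Ankrd37 (12.4 ± 5.43 to 0.823 ± 0.200 FPKM; -2.82, SE 0.27), Nxt2 (-2.75, SE 0.15), Sohlh2 (-2.56, SE 0.19), Mael (-2.46, SE 0.21), Ufsp2 (-2.38, SE 0.18), Dctd (-2.28, SE 0.12) and the lymphotoxin gene Ltb (-2.28, SE 0.21) fell, and the precursor Mir186 (-2.26) is uncertain.

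Of 11420 genes tested at day 9, 221 were higher and 402 lower, 61 and 190 of them by at least 1 on the log2 scale, and total-read scaling gave 122 higher and 392 lower. Germline genes fell in 10 of 13 cases and 1 rose (11 and 2 adjusted over the list alone; median -1.32, camera adjusted p = 3.42e-07, adjusted p = 0.565 with an estimated correlation). The lower ones included Dazl (-1.72, SE 0.16), Ddx4 (8.41 ± 0.762 to 2.33 ± 0.350 FPKM; -1.50, SE 0.15) and Tex11 (-1.87, SE 0.19). The p53 targets rose in 8 of 17 cases with 0 lower (11 and 0 adjusted over the list alone; median 0.56, camera adjusted p = 4.27e-09, adjusted p = 0.484 with an estimated correlation). Risers included Plk2 (18.7 ± 2.25 to 50.7 ± 2.28 FPKM; 1.4, SE 0.13), Perp (1.1, SE 0.11), Mdm2 (0.95, SE 0.12) and Ccng1 (0.79, SE 0.12). Histones had 2 of 8 higher by both adjustments (Hist1h4i 1.00, Hist1h2bc 0.69; median 0.45, camera adjusted p = 0.0054, adjusted p = 0.565 with an estimated correlation).

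Lists not called at day 9 had these members past the gene test. The epiblast list (11 tested, camera adjusted p = 0.176) had Pou3f1 (1.07), Dnmt3a (0.65) and Dnmt3b (123 ± 10.3 to 215 ± 41.8 FPKM; 0.79) higher. Also higher were, in the endoderm list (8, 0.125), Afp and Dab2 (1.26), in the neural list (8, 0.221), Nefl (23.1 ± 2.94 to 50.3 ± 1.47 FPKM; 1.09) and Olig2 (0.95), and in the primitive streak list (13, 0.593), Nodal (32.1 ± 1.60 to 55.6 ± 7.35 FPKM; 0.77). Pluripotency (22, 0.246) had Prdm14 lower (14.6 ± 0.569 to 5.22 ± 2.69 FPKM; -1.40), with Nanog at -0.82 (adjusted p = 0.0791). Trophoblast (7, 0.178) had Tfap2c (-1.03), Rhox9 (-1.36) and Rhox6 (-1.17) lower and Ascl2 (0.88) higher. The Rhox genes are a multigene family and uncertain. Des (1.06) was higher in the cardiac list (3, 0.593), where 2 were lower adjusted over the list alone (median -0.62). Thy1 (0.77) was higher in fibroblasts (5, 0.593; median -0.10, mean 0.03, camera direction higher) and Atf3 (1.33) in immediate early genes (9, 0.178). Pecam1 (-0.63) was lower in blood and endothelium (6, 0.178), Phf19 (-1.14) in Polycomb (29, 0.176) and B2m (-0.74) in housekeeping (13, 0.593), while COMPASS (16, 0.593) and other developmental factors (14, 0.178) had 0 past the test. Day 6 and day 9 shared 284 lower genes, against 30.0 for independent lists (Fisher's exact p = 1.62e-244), and 133 higher, against 11.8 (p = 5.71e-115). Calls numbered 255 and 92 without WT replicates 1 and 2, 1109 and 1084 without KO replicates 1 and 2, 346 with a filter at 5 FPKM and 1811 with the spread pooled over the 16 RNA libraries, against 623. Without a filter limma called 0 (3945 unadjusted, against 2760 with it; voom with the filter 603).

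**Figure D3:**
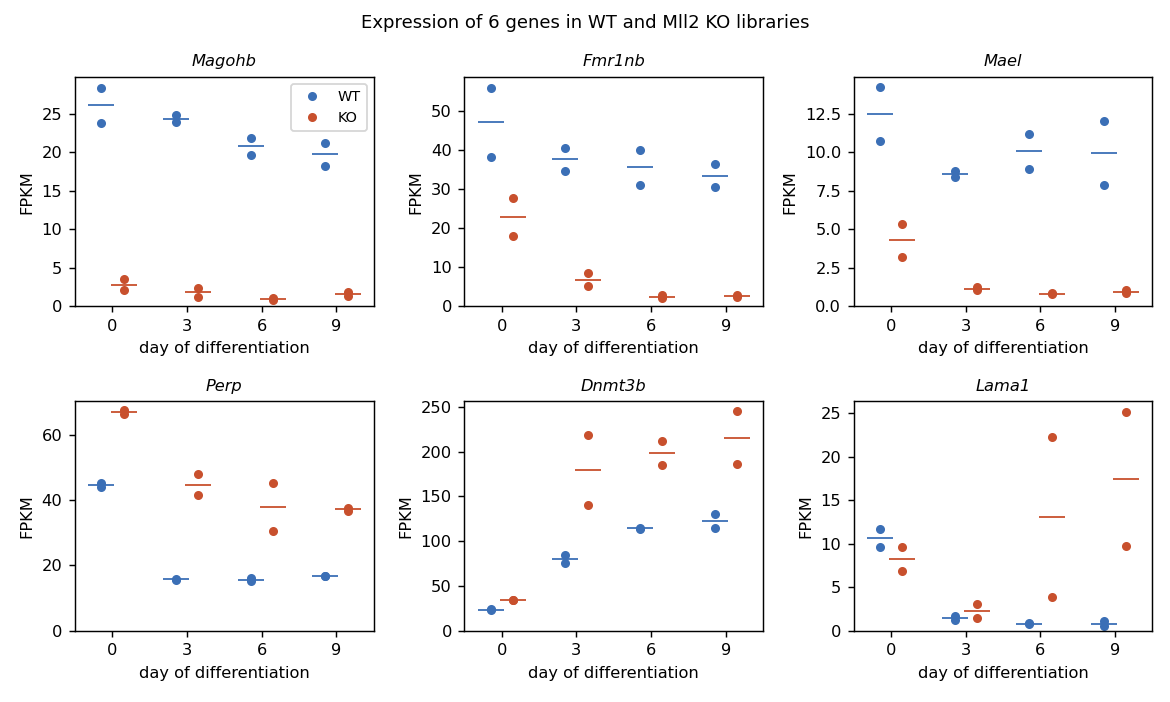
FPKM of Magohb, Fmr1nb, Mael, Perp, Dnmt3b and Lama1 (y axes) at days 0, 3, 6 and 9 (x axis) in WT and KO, with points for libraries and lines for means, the 6 genes having been chosen after their values were seen. At day 9 mean Magohb was 19.8 FPKM in WT and 1.59 in KO, and mean Lama1 0.821 in WT and 17.4 in KO.

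Whether the KO effect itself changed during differentiation was tested against day 0 in 11368 genes. The effect differed at 152 genes at day 3 (57 with a higher and 95 with a lower KO to WT ratio than at day 0), at 218 at day 6 (64 and 154) and at 228 at day 9 (92 and 136). Tspan7 fell at day 0 (-2.09) and was at -0.05 at day 3 (difference 2.04, SE 0.24, limma adjusted p = 0.00446) and 0.23 at day 9 (difference 2.32, SE 0.24, adjusted p = 0.0018). Pim2 went from 0.53 at day 0 to 2.24 at day 3 (1.71, SE 0.29, adjusted p = 0.022), Nes from 0.04 to 1.80 (1.76, SE 0.39, adjusted p = 0.0464), and Nrep from -0.67 to 1.19 (1.86, SE 0.17, adjusted p = 0.00109). The Wnt inhibitor Apcdd1 went from 2.17 to 0.18 (-1.99, SE 0.34, adjusted p = 0.022) and Aard from 0.68 to -1.50 (-2.18, SE 0.26, adjusted p = 0.00446). At day 6, Cubn went from 0.11 to 2.60 (2.49, SE 0.57, adjusted p = 0.044), and the growth regulator Gpc3 from -1.70 to -0.04 (1.66, SE 0.19, adjusted p = 0.00173). The MHC class II gene H2-Eb1 went from 1.34 to -1.57 (-2.91, SE 0.49, adjusted p = 0.013) and Fmr1nb from -1.02 to -3.36 (-2.34, SE 0.34, adjusted p = 0.00807). At day 9, Lama1 went from -0.35 to 3.21 (3.56, SE 0.80, adjusted p = 0.0425), Srgn from -0.24 to 2.93 (3.16, SE 0.70, adjusted p = 0.0413), and the laminin chain Lamb1 from -0.17 to 1.38 (1.55, SE 0.27, adjusted p = 0.015). Ankrd37 went from -0.42 to -2.82 (-2.40, SE 0.36, adjusted p = 0.01) and Aire from 1.61 to -0.74 (-2.35, SE 0.36, adjusted p = 0.01).

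Counts with a library left out do not show whether these differences rest on single libraries. A group left with 1 library gives a less precise effect, so calls can be lost whichever library is dropped. Only the runs that moved most are given here. The others moved less, and the count rose at day 3 without day 3 KO replicate 2 and at day 9 without day 0 WT replicate 1. At day 3 the count of 152 was 27, 86 and 16 without day 0 WT replicates 1 and 2 and KO replicate 1, and 10, 11 and 12 without day 3 WT replicates 1 and 2 and KO replicate 1. At day 6 the count of 218 was 141, 76 and 137 without day 0 WT replicate 2 and KO replicates 1 and 2, and 30, 74 and 33 without day 6 WT replicates 1 and 2 and KO replicate 1. At day 9 the count of 228 was 118 and 75 without day 0 WT replicate 2 and KO replicate 1, and 107 and 59 without day 9 WT replicates 1 and 2.

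The same lists were followed over time within each genotype. Between day 0 and day 9, 2484 genes were higher and 2408 lower in WT, and 2792 and 2600 in KO, with tables normalized separately. In WT, all 11 epiblast genes were higher at day 9 (median 2.33; KO 11 of 11, median 2.95). In the same cells 7 of 10 primitive streak genes were higher (median 2.24; KO 8 of 10, median 1.84). Of 22 pluripotency genes, 13 were lower and 4 higher in both genotypes (medians -0.84 in WT and -0.95 in KO). Germline genes were lower in 6 of 13 cases in WT and in 10 of 13 in KO (medians -0.52 and -1.13), and the KO effect on them differed between day 9 and day 0 for 2 of 13. Endoderm genes were higher in 2 and lower in 1 of 6 in WT, and higher in 4 and lower in 1 in KO. At day 9 the limma test of that difference passed for no endoderm, epiblast, primitive streak or pluripotency gene, so their counts at day 9 do not show a difference between genotypes. Earlier, the KO effect was higher than at day 0 for 2 of 11 epiblast genes at day 3. At day 6 it was higher for 1 of 11 epiblast and 1 of 10 primitive streak genes.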

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

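Tests chosen only after the result was seen were the median of X-linked genes, both endoderm tests and the H3K4me3 comparison with equal numbers of peaks. The Fisher's exact tests by chromosome were not among the planned tests either. The effect of the KO differed from day 0, by a limma test of the difference itself, at 152 genes at day 3, 218 at day 6 and 228 at day 9. Between experiments 1 and 2 the Suz12 difference at bivalent regions was 1.8 and -5.3 points and the Ring1b difference -6.0 and 24.5 points, opposite directions whose difference was not tested, while equal numbers of peaks gave -3.8 and -4.8 for Suz12 and -4.7 and 2.4 for Ring1b. The H3K27me3 difference was 7.6 points in experiment 2 and 0.6 in experiment 1 for the KO and -4.4 points for CD cells, and the difference between the lines was not tested. In experiment 1 the WT share of 97.7% left little room for a gain.

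X-linked genes were over-represented among genes lower in the KO at day 0, 36 of 426 tested (8.45%) against 175 of 10560 on other chromosomes (1.66%; Fisher's exact p = 3.85e-14), with chromosome 6 next at 3.02%, and 18 of 491 against 0.71% in PRO-seq (p = 8.63e-08). Easier calls at the expression levels of X-linked genes are argued against, since autosomal genes of the same mean FPKM gave 6.61 expected calls against 36 (Poisson interval 25.2 to 49.8). Fewer X chromosomes in most KO cells would lower all X-linked genes alike. The median of X-linked minus autosomal genes was -0.10 (-0.12 to -0.07, bootstrap over genes), and that of called X-linked genes -1.32. The interval does not measure the spread between cultures. Loss in a small share of cells was not excluded, since the median of X-linked minus autosomal genes lies below 0. The excess was also present at day 3 (21.85% against 11.07%), day 6 (13.46% against 7.64%) and day 9 (9.47% against 3.24%). What sets these genes apart stays open, since deletion and tamoxifen came together and no biological explanation was tested.

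Endoderm markers were higher in the KO at day 6 with a wide spread, Col4a1 being 1.86 and 2.18 FPKM in WT and 46.1 and 8.02 in KO. Of 21 endoderm markers outside the 10 largest changes per direction of any comparison, 17 (81%) were higher in both KO than in both WT libraries. So were 26 of all 30, against 12 at day 0, 20 at day 3 and 19 at day 9. Krt8, Krt18, Sox7 and Lamb1 are among the 21 and named above, so the 21 are not an independent set. Of all genes tested at day 6, 61.8% had replicates that did not overlap between genotypes, in either direction. Material in KO replicate 1 alone is argued against by KO replicate 2, though by that 1 library only. Its median log2 ratio to WT over the 21 markers was 0.48 (0.15 to 0.55, bootstrap over markers). The interval treats related genes as independent and does not measure the spread between cultures. KO replicate 1 lay above KO replicate 2 in 29 of 30. A larger share of endoderm-like cells in the KO cultures may account for the pattern and stays open, with Apoe (554 and 535 FPKM in WT, 320 and 494 in KO) against the direction. Whether the cells changed in number or each cell in expression was not tested.

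H3K4me3 peaks were absent in the KO at more of the bivalent than of the H3K4me3-only regions. Weaker peaks nearer to the calling threshold are argued against, since within bins of similar WT peak score the difference in loss was 26.8 points (28.6 in experiment 2, 25.1 in experiment 1). Without matching it was 13.2, but the widening is not evidence. In experiment 2 the lowest bin held 1850 of 9249 bivalent and 12036 of 27201 H3K4me3-only regions. In experiment 1 it held 849 of 4245 and 13978 of 27901. Tied scores put 3596 bivalent regions of experiment 2 in 1 bin, so the matching was loose. Shorter KO lists alone are argued against by bivalent regions at equal numbers of peaks. They stood at 85.8% in WT and 50.7% in KO in experiment 2, and at 94.6% and 61.4% in experiment 1. The gap between the classes was then -32.5 points, against -19.3 with the full lists, but its widening is not evidence. In experiment 2 trimming took WT H3K4me3-only regions from 81.9 to 61.0% and WT bivalent regions only from 94.8 to 85.8%. Bivalent regions without a WT MLL2 peak had larger differences (-62.0 and -58.4 points) than those with one (-22.7 and -16.8), but not in every bin of the same WT score, where the loss with an MLL2 peak was the higher in 3 of 5 bins in experiment 2 and 1 of 4 in experiment 1, so a role of bound MLL2 is neither excluded nor shown. Why bivalent regions differ stays open, and tamoxifen, the peak caller's control, spike-in use and the single library per genotype and experiment were not tested as sources.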

How the results depend on the processing

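Alternatives chosen only after the result was seen were voom on recovered reads, total-read scaling and the day 6 lists without KO replicate 1. Where a library was left out, the lone sample of its group was assumed to vary like the other group. The cause was not tested for any moved or reversed value unless given.

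Without a filter on low values, which tests more genes, the counts were 0, 959, 333, 0 and 0 at days 0, 3, 6 and 9 and in PRO-seq, against 376, 2356, 1490, 623 and 218. At 5 FPKM, with fewer genes tested, they were 72, 1425, 894, 346 and 68. With the replicate number as a block they were 2007, 3667, 2537, 1398 and 1290, but numbers do not establish pairs (correlations of same-numbered changes 0.57, 0.36, 0.25, 0.31 and 0.36). With pooled spread day 0 gave 1134 and day 9 gave 1811. PRO-seq gave 850 with voom and 91 by total reads. With 1 library left out the ranges were 0 to 511, 151 to 3059, 157 to 2684, 92 to 1109 and 0 to 31. Pseudocount 0.1, quantile normalization and no trend stayed within 1.5 times. The KO effect differed from day 0 at 559, 607 and 736 genes with the block, and at 10 to 212, 30 to 174 and 59 to 307 with 1 library left out. Kmt2b at day 0 (-0.14) ranged from -0.292 without WT replicate 1 to 0.005, a reversal, without WT replicate 2. No other named gene reversed: of 229 gene results 210 kept direction and call with voom, 212 by total reads, 69 without the filter, 104 without WT replicate 1 and 86 without WT replicate 2.

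Called lists numbered 0 in every comparison with an estimated correlation (0, 0, 1, 1 and 0 at an unadjusted p under 0.05), 0, 5, 1, 0 and 0 with fry (2, 4 and 4 unadjusted where 0), against 1, 8, 10, 3 and 4. The fry calls at day 3 were Polycomb and germline genes lower and p53 targets, fibroblast and neural genes higher. At day 6 fry called the germline list lower. With the replicate number as a block day 6 gave 9, the primitive streak list going from a camera adjusted p of 0.0416 to 0.0572. The block gave 4 at day 0, p53 targets (0.000983), germline lower (6.21e-05, against 0.0919), and cardiac and immediate early genes higher (0.0378 each, against 0.0919 and 0.156), and day 6 without KO replicate 1 gave 10.

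With equal numbers of peaks the H3K4me3 differences were -34.15 points at bivalent and -1.62 at H3K4me3-only regions in the KO (-40.84 and -21.52 with full lists) and -10.82 and -6.05 in CD cells (-17.23 and -28.15). Ring1b reversed to -1.17 (9.28), serine 5 polymerase gave -24.04 (-12.88), RPB1 5.19 (11.79), H3K27ac -0.31 (-2.90) and MLL2 marking 0.39 (28.42), by construction since 264 peaks remain. In regions with an MLL2 peak H3K4me3 gave -19.74 and -4.64 in the KO and -3.34 and -4.17 in CD, H3K27me3 -1.93 in CD (-4.45), Suz12 reversed to 1.22 (-1.79), serine 5 polymerase -15.98, RPB1 14.33, H3K27ac -4.98 and re-ChIP marking 91.47 (77.22). In regions with a re-ChIP window H3K4me3 gave -36.14 in the KO and -12.63 in CD, H3K27me3 -3.49 in CD, serine 5 polymerase -14.35 and MLL2 marking 33.54. Overlap of 0.5 gave H3K27me3 9.97 in the KO (4.10) and -3.58 in CD. ATAC differences ranged from -8.09 to -1.27 at bivalent regions and from -5.85 to -1.96 for the classes.

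Not run were the bivalent genes test with its alternatives, for want of an mm9 annotation, the pooled spread for PRO-seq, MLL2 and re-ChIP marking within regions chosen by themselves, and re-ChIP regions for the H3K4me3-only class. Depth may limit calls of low genes, which was not tested, and 1.5-fold changes were recovered in 9.0 to 59.7% of simulated genes.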

Other observations

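The values of this part were picked after they were seen and were not tested. Polycomb proteins were also measured at H3K4me3-only regions. These regions were chosen for having no WT H3K27me3 peak, which may hold WT shares low and favour a gain in the KO. Shares with equal numbers of peaks were not computed for the subset with an MLL2 peak. Among the 6232 of these regions with an MLL2 peak, Suz12 was at 0.7% (0.5 to 1.0) in WT and 5.7% (5.1 to 6.3) in KO in experiment 1, and at 2.2% (1.8 to 2.6) and 5.9% (5.3 to 6.5) in experiment 2. Among the 20870 regions without an MLL2 peak it was at 0.1% and 0.3%, and 0.7% and 0.5%. Ring1b at regions with an MLL2 peak was at 22.4% and 24.2% in experiment 1 and at 0.1% and 4.7% in experiment 2, and at regions without one at 5.0% and 3.4%, and 0.0% and 0.2%. With equal numbers of peaks, Suz12 at all H3K4me3-only regions was at 0.3% and 0.8% in experiment 1 and 0.9% and 1.7% in experiment 2, and Ring1b at 6.6% and 8.2%, and 0.0% and 0.1%.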
